A study of Homo sapiens with 8 samples.

How the data were processed

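Cells of the CAL27 and SCC13 lines were crosslinked with 1% formaldehyde for 10 min, and chromatin was immunoprecipitated with 10 ug of p63 antibody, per the labels' protocols. The submitters' processing notes name Bowtie2, SAMtools 1.8, MACS2 and the build hg19, without roles or order. The peak threshold, the use of the samples titled none, and the way replicates were combined are not given in the sources used here. The authors deposited 1 list of regions per line with 3 columns, chromosome, start and end, and no score, height, summit or p-value for a region. The labels name each list for both p63 replicates of its line, so replicates could not be compared. Positions are printed counted from 1.

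Regions were matched by an overlap of at least 1 bp. Overlap and clustering were set against 1000 random placements with widths kept, either anywhere on the same chromosome or within 500 kb, with midpoints outside centromeric, variable and stalk bands. Such placement takes no account of open chromatin or mappability, so it is a lenient comparison. A p-value for the overlap had been planned from these placements and was dropped after the overlapping regions proved identical in both lists. Clusters joined midpoints within 12500 bp and needed 5 or more regions. Shares per chromosome were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment at 0.05. Intervals of percentages are exact Clopper-Pearson at 95% and those of ratios use the normal approximation on the log scale; both cover counting error only. Regions were treated as independent, which makes p-values too small where neighbours depend on each other. In the tests of shares, shared regions were counted in both lists, so the lists compared were not separate samples. The exact test and the ratio intervals do not allow for this. By itself it makes p-values too large and intervals too wide.

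No genome or annotation of hg19 was given as a reference. Chromosome lengths and cytogenetic bands of hg19 were taken from tables supplied with the R packages GenomeInfoDb 1.38.1 and circlize 0.4.16, under R 4.3.3; arms, band classes and placements rest on them. A placement from the listed positions alone, between the first and last region of a chromosome, was added as an alternative. The reference table of gene names is of GRCh38, another build, and was not used. Gene models were therefore left out, and the rule for naming items fell back to regions, as fixed before the data were examined: the 5 widest regions and the 5 clusters with the most regions per line. Ties of clusters were broken by the shorter span, which that rule had not fixed. Genomic location, motif content (15 motifs), 17 gene lists and peak scores had been planned and were not analysed here. An exploratory pass had counted regions near bundled gene models; it was set aside as outside these rules, and no value from it is reported.

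The counts, overlap, chromosome shares and clusters, with their alternatives, were chosen before the data were examined. Widths, arms, band classes, runs of neighbouring regions, neighbourhoods and the added alternatives were chosen after the values had been looked at. The set of patterns weighed in the closing section was also revised after first results: a count over the arms that had passed was replaced by a correlation over all arms, and tests of the darkest bands were added. Mean log2 widths were compared by permutation with 100000 resamples, two-sided, and runs and rotations used 1000 draws. Arms with at least 20 regions were tested. Each chromosome and arm was also set against the rotations, two-sided, by its log2 ratio with 0.5 added to each count and with the same adjustment; a rotation carries any excess along whole arms with it, so this is a strict comparison. Alternatives of the overlap rule and the neighbourhoods used 200 placements, whose smallest p is 0.00498.

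Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The functions were tested on simulated data: 1500 of 1500 copied regions were found as shared, 0 of 20 pairs of independent lists gave p under 0.05, and 30 of 30 planted clusters were found. For shares over 23 chromosomes, 96.5% of 200 simulated 1.5-fold changes and 0.727% of 4400 unchanged chromosomes were called. The simulated lists for these shares had no regions in common and no runs, unlike the deposited lists, so these rates may not hold for them. Of 2300 unchanged chromosomes with classes simulated in runs, 4.91% had a rotation p under 0.05.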

Results

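Binding of p63, the transcription factor encoded by TP63 that marks basal keratinocytes and squamous tumours, was profiled by chromatin immunoprecipitation and sequencing in CAL27 and SCC13, 2 established human squamous cell carcinoma lines. The 8 samples formed 4 groups of 2: p63 immunoprecipitation and samples titled none, in each line. The title of the series names p63 and a cofactor in squamous carcinoma; the comparison open to the files used here was that of p63-bound regions between both lines. The deposited data were 1 list of regions per line, in hg19 coordinates, with both replicates behind each list. No spread between replicates could be computed, no sequencing depth was given, and the p-values compare these 2 lists, with regions treated as independent.

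CAL27 had 13829 listed p63 regions and SCC13 had 5886, so that the CAL27 list was 2.35 times as long. The CAL27 regions covered 12.0 Mb and the SCC13 regions 5.46 Mb. The median region was 791 bp wide in CAL27 and 862 bp wide in SCC13. Regions lay on all 22 autosomes and on X. Without depths or scores, the difference in length cannot be assigned to the cells.

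Of the 5 widest regions of each list, all 5 of SCC13 and 3 of CAL27 were shared. Shared regions had identical start and end positions in both lists, so their widths necessarily matched. The widest in each list was the same 3456 bp region on chromosome 3 at 159480918 to 159484373, in band 3q25.33. It was followed in both lists by a 3420 bp region on chromosome 1 at 153537808 to 153541227 in band 1q21.3, the band of the epidermal differentiation complex, and by a 3335 bp region at 32039509 to 32042843 in band 1p35.2. The next widest CAL27 regions, of 3234 bp on chromosome 17 at 60745713 to 60748946 and of 3223 bp on chromosome 16 at 87885100 to 87888322, were absent from the SCC13 list. The next widest SCC13 regions, of 3113 bp on chromosome 9 at 138999280 to 139002392 and of 2969 bp on chromosome 15 at 70486377 to 70489345, were also in the CAL27 list. Genes, exons and introns at these positions were not analysed here.

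Most p63 regions of SCC13 were also p63 regions of CAL27. Of the 5886 SCC13 regions, 4448 overlapped a CAL27 region, or 75.6% (95% exact binomial interval 74.5 to 76.7). The reverse share was 32.2% of the CAL27 regions (31.4 to 33.0). The remaining 9381 regions were listed in CAL27 only and 1438 in SCC13 only. Random placement of the SCC13 regions on their own chromosomes gave 55.2 ± 7.60 overlaps (SD, 1000 placements) and never more than 77, and placement within 500 kb of each region gave 98.9 ± 9.32, at most 126. All 4448 overlapping regions had identical start and end positions in both lists, as regions drawn from a common set have. Free placement breaks up such a set, so these numbers describe unrelated positions and do not test how far binding was shared, and no p-value is given for the overlap. With the CAL27 list reduced at random to the length of the SCC13 list, 32.6% of SCC13 regions were shared. Identical positions and random removal fix this value near the reverse share of 32.2%, so it does not correct the sharing for list length.

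Shared regions were wider than regions listed in 1 line, a comparison chosen after the values were seen. The geometric mean width was 956 bp for shared regions, 743 bp for CAL27-only regions and 606 bp for SCC13-only regions. Shared regions were 1.29 times as wide as CAL27-only regions (95% interval 1.27 to 1.30) and 1.58 times as wide as SCC13-only regions (1.54 to 1.61). CAL27-only regions were 1.22 times as wide as SCC13-only regions (1.20 to 1.25). Each of the 3 two-sided permutation tests of log2 width gave an adjusted p of 1.00e-05, the smallest that 100000 resamples can give. With each list divided by width into 5 groups of equal size, the shared percentage in CAL27 rose from 9.87% (8.78 to 11.0) in the narrowest group to 50.9% (49.0 to 52.7) in the widest. In the SCC13 list it rose from 34.9% (32.2 to 37.7) to 94.8% (93.4 to 96.0). Width is not a measure of binding strength, and regions merged across lines can be wider for that reason.

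**Figure D1:**
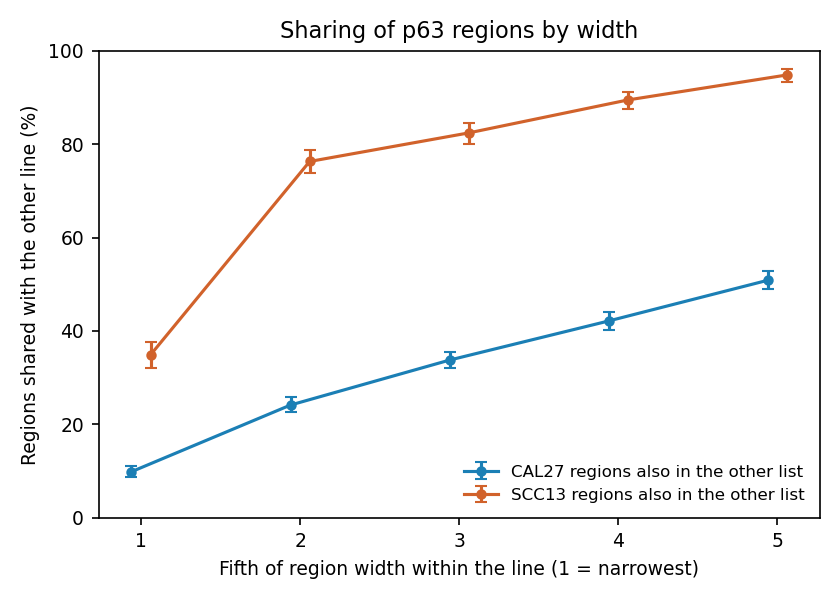
The horizontal axis gives 5 groups of equal size by region width within each list, from narrowest to widest, and the vertical axis the percentage of regions also found in the other line, with points for each line and bars for 95% exact binomial intervals. The percentage rises from 9.87% to 50.9% in CAL27 and from 34.9% to 94.8% in SCC13.

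The share of p63 regions on 4 chromosomes differed between the lines by exact test, and on chromosome 4 also when runs of neighbouring regions were allowed for. Chromosome 4 held 5.10% of the SCC13 regions and 3.57% of the CAL27 regions, a ratio of 1.43 (95% interval 1.24 to 1.64; Fisher's exact test, adjusted p = 2.45e-05). Chromosome 8 held 5.35% and 4.06%, a ratio of 1.32 (1.15 to 1.51; Fisher's exact test, adjusted p = 8.25e-04). Smaller shares in SCC13 were found for chromosome 2, with a ratio of 0.868 (0.781 to 0.964; exact test, adjusted p = 0.0455), and for chromosome 9, with a ratio of 0.817 (0.706 to 0.944; adjusted p = 0.0455). These 4 of 23 chromosomes passed Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. The density of regions was highest on chromosome 17 in CAL27, at 7.18 per Mb, and on chromosome 20 in SCC13, at 3.00 per Mb. It was lowest on X in both, at 1.79 and 0.895 per Mb. When regions within 12500 bp were counted once, chromosome 2 no longer passed the exact test (adjusted p = 0.0891), and without shared regions the ratio of chromosome 4 was 2.22. Against class labels rotated along the genome, which keeps runs of neighbouring regions, only chromosome 4 of the 23 passed (permutation, adjusted p = 0.0230), with 0.195 for chromosome 8 and 0.391 for chromosomes 2 and 9.

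Among single chromosome arms, a division added after the data were examined, the largest difference was on 8p. Of 41 arms tested in the same way, 6 passed, and neither arm of chromosome 2 was among them. By exact test, SCC13 had the larger share on 8p, with a ratio of 2.00 (95% interval 1.48 to 2.69; adjusted p = 3.23e-04), on 3p, with 1.48 (1.21 to 1.82; adjusted p = 0.00290), on 4p, with 1.45 (1.12 to 1.89; adjusted p = 0.0368), and on 4q, with 1.42 (1.20 to 1.68; adjusted p = 0.00156). By the same exact test, CAL27 had the larger share on 3q, with a ratio of 0.773 (0.663 to 0.902; adjusted p = 0.0101), and on 9q, with 0.782 (0.662 to 0.923; adjusted p = 0.0294). The arms of chromosome 3 lay on opposite sides of an equal share, and the whole chromosome had a ratio of 0.965 (0.856 to 1.09; exact test, adjusted p = 0.787). Of the 6, only 8p passed against rotated class labels (permutation, adjusted p = 0.0410, with 0.143 to 0.414 for the others), and 4p also fell short when regions within 12500 bp were counted once (exact test, adjusted p = 0.130). Without shared regions, which add equally to both lists, the 6 ratios moved farther from 1, to 4.73 on 8p, 2.56 on 3p, 2.32 on 4p, 2.17 on 4q, 0.475 on 3q and 0.472 on 9q, and 5 further arms passed the exact test, 2q (adjusted p = 9.39e-04), 8q (0.0222), 18q (0.00681), 22q (0.00198) and Xq (0.00106). Against rotated class labels, with shared regions kept, none of these 5 further arms passed (permutation, adjusted p from 0.414 to 0.786).

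**Figure D2:**
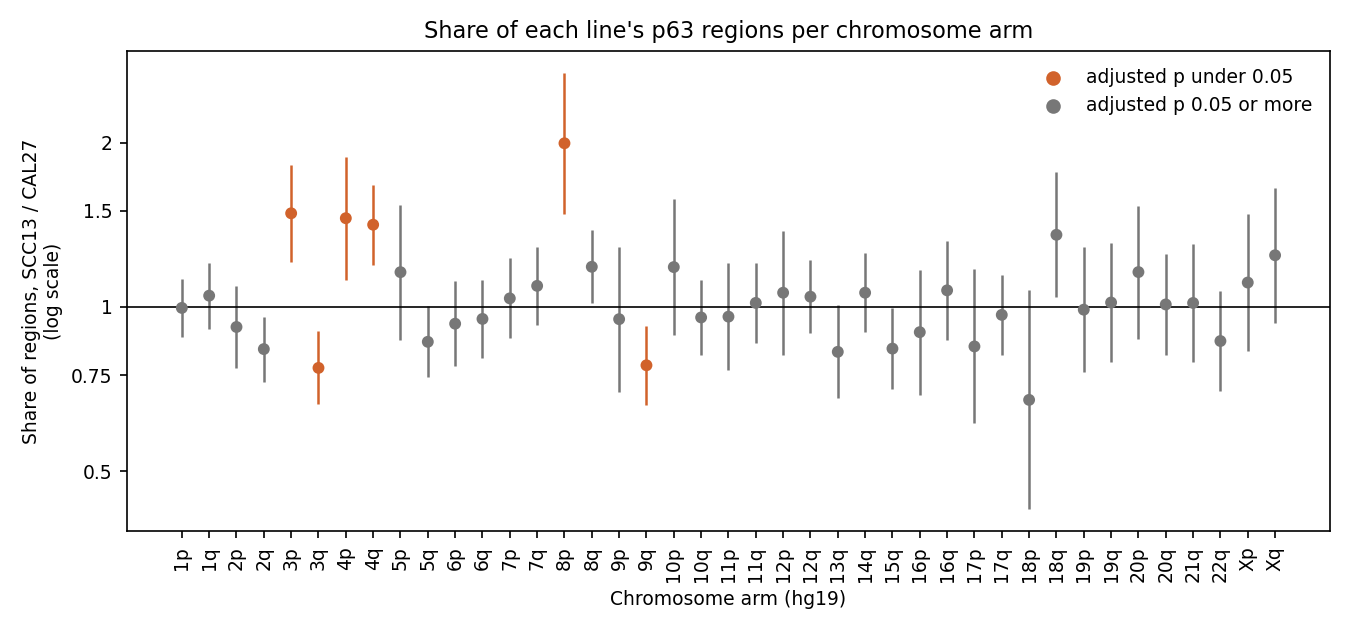
The horizontal axis gives the 41 chromosome arms and the vertical axis, on a log scale, the share of SCC13 regions on an arm divided by the share of CAL27 regions, with bars for 95% intervals and orange for an adjusted p under 0.05. Arm 8p has the highest ratio, at 2.00, and arms 3p and 3q lie on opposite sides of an equal share.

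Regions of p63 were crowded into clusters more than placed regions were. In CAL27, 13 clusters held 5 or more regions with neighbouring midpoints within 12500 bp, against 0.313 ± 0.569 (SD) for placement on the same chromosome (one-sided permutation p = 9.99e-04, the smallest possible) and 2.28 ± 1.49 for placement within 500 kb (p = 9.99e-04). SCC13 had 1 such cluster (one-sided permutation p = 0.00599; p = 0.0360 for placement within 500 kb). The CAL27 cluster with the most regions held 7, on chromosome 1 at 3597452 to 3634369, in band 1p36.32, and 5 of them were shared. Clusters of 6 lay on chromosome 6 at 56507331 to 56533555, in band 6p12.1, with 2 regions shared, and on chromosome 19 at 38456538 to 38495695, in band 19q13.13, with 3 shared. The next 2 held 5 regions each, on chromosome 6 at 36634538 to 36650984, in band 6p21.2, with 3 shared, and on chromosome 8 at 49608580 to 49626684, in band 8q11.21, with all 5 shared. That chromosome 8 cluster also held the most regions of any in SCC13. The next groups of neighbouring regions in SCC13 held 4 each, fewer than the 5 that define a cluster; the naming rule, with ties broken by the shorter span, took those on chromosome 7 at 43607969 to 43626453, chromosome 1 at 3597452 to 3616248, chromosome 9 at 117549362 to 117570532 and chromosome 2 at 31601693 to 31624989. It left out 1 further group of 4, on chromosome 6 at 30843760 to 30870448. The number of clusters depended strongly on the joining distance, from 1 at 5 kb to 76 at 25 kb in CAL27 and from 0 to 7 in SCC13.

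**Figure D3:**
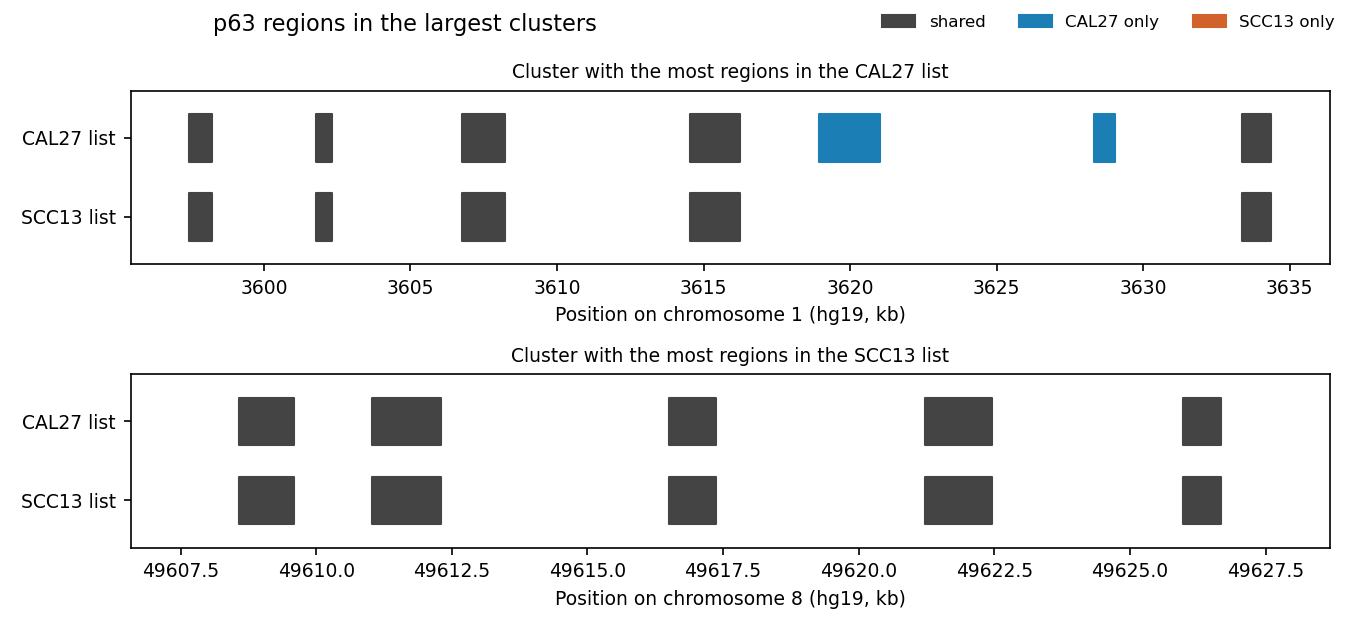
Each panel has the hg19 position in kb on the horizontal axis and a row for each line's list, with boxes drawn to scale for regions, grey where shared and blue where listed in CAL27 only. The chromosome 1 cluster has 7 CAL27 regions, 5 of them shared, and all 5 regions of the chromosome 8 cluster are shared.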

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

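The tests in this part were chosen after the results they bear on had been seen, except the chromosome shares themselves. A test of the difference between lines picked out 4 chromosomes and 6 arms whose share of p63 regions differed. The SCC13 to CAL27 ratios were 0.868 for chromosome 2, 1.43 for chromosome 4, 1.32 for chromosome 8 and 0.817 for chromosome 9. For arms they were 1.48 on 3p, 0.773 on 3q, 1.45 on 4p, 1.42 on 4q, 2.00 on 8p and 0.782 on 9q.

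Local runs of line-only regions did not account for all of the heterogeneity over arms: after the class labels were rotated along the genome, which keeps such runs, the chi-square over arms averaged 74.9 and reached 104 at most, against 125 observed (p = 9.99e-04, the smallest of 1000 rotations). For most single arms and chromosomes such runs were not excluded, since 8p (permutation, adjusted p = 0.0410) was the only one of the 6 arms and chromosome 4 (adjusted p = 0.0230) the only one of the 4 chromosomes to pass against the same rotations, with adjusted p from 0.143 to 0.414 for the others. A copy-number difference of whole arms may contribute, as a hypothesis: across 41 arms, the log2 ratios of the first and last parts of an arm, split at its middle region, correlated with Pearson's r = 0.718 (permutation p = 1.00e-05, the smallest possible) and Spearman's rho = 0.630 (p = 2.00e-05), and r was 0.604 without the 2 arms farthest from the median. With a small constant added to each count, r was 0.720 against a mean of 0.268 and at most 0.652 in the rotations (permutation p = 9.99e-04), but in the 35 arms that had not passed, r fell to 0.431 (permutation p = 0.00967), with both parts on the same side of an equal share in 23 of the 35, and 0.428 with the constant added did not pass the rotations (mean 0.267, at most 0.683, permutation p = 0.202); these arms were chosen by their ratios, so this does not show where the excess lies. Regulation on the scale of an arm would give the same correlation, and neither copy number nor input signal was used here, so both stay open. The 4 arms with larger SCC13 shares had 2.04 to 2.92 CAL27 regions per Mb, against 4.55 over all chromosomes. The arms with smaller shares, 3q and 9q, had 5.85 and 5.83. CAL27 counts are part of the ratios that chose these 6 arms, so this contrast is partly built in. In SCC13 the arms with larger SCC13 shares had 1.48 to 1.81 regions per Mb, against 1.94 over all chromosomes. Arms 3q and 9q had 1.92 and 1.94 in SCC13. Arms 9p, 18q, Xp and Xq, with 1.44 to 2.88 CAL27 regions per Mb, did not pass the exact test with shared regions kept. Background among SCC13-only regions, raised below for the darkest bands, was not tested for arms. Such regions cannot raise the percentage of CAL27 regions that are shared. It was 39.4 to 45.2% on the 4 arms with larger SCC13 shares and 27.6% and 28.1% on 3q and 9q, against 32.2% overall. These values argue against such background as the whole difference, though the ratios that chose the 6 arms count shared regions. On the 4 arms 53.2 to 67.0% of SCC13 regions were shared, against 75.6%, so background as a part stays open.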

How the results depend on the processing

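No paired analysis was possible because the labels number 2 replicates per group but each line has 1 pooled list. For the same reason no replicate was left out. Stricter thresholds were not run, since regions have no score, nor were alternatives for location, motifs and gene lists; leaving out line-only regions makes both lists identical, so it was void. Alternatives added after the data were examined were the arms, the omission of shared regions, the regions wider than the median of their list, rotation of the class labels, placement from listed positions alone, and those for widths and bands. The shared 75.6% was the same under all 3 other overlap rules, which identical coordinates ensure. It was 32.6% with the CAL27 list reduced at random, as fewer regions could match, and 90.5% between the regions wider than the median of their list. The wider SCC13 regions had the same 90.5% in the whole CAL27 list, which identical widths and the larger SCC13 median ensure. The narrower ones had 60.6%, so the rise came from leaving out narrow SCC13 regions. The 4 chromosome calls became 3 with neighbours counted once, 6 without shared regions and 1, chromosome 4, against rotated class labels, and the 6 arm calls became 1, 8p, against these, a stricter test that allows for runs of neighbouring regions; by exact test, chromosome 2 (adjusted p = 0.0891) and arm 4p (adjusted p = 0.130) fell short with neighbours counted once, and no ratio of these chromosomes and arms changed direction. Without shared regions 11 arms passed in place of 6, and the ratios of chromosome 4 and of all 6 arms moved by over 1.5 times, 8p the most (2.00 to 4.73). Clusters in CAL27 numbered 13, against 1 at 5 kb, 76 at 25 kb and 309 with 3 or more regions; in SCC13 they numbered 1, against 0, 7 and 25, as the joining rule itself dictates. The 5 kb excess in CAL27 was not past the threshold for placement within 500 kb (permutation p = 0.0619). The excess of SCC13-only over CAL27-only regions in the darkest bands and the greater width of shared regions kept their direction and their side of the threshold without X and without the 6 arms; the other width and band comparisons were not rerun. The depth of the libraries is unknown, so a region missing from a list is not shown to be unbound.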

Other observations

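The band comparisons and all tests in this part were chosen after the data had been examined, and the tests within groups of width and within arms were set out before their own results were seen. Both p63 lists favoured the pale, gene-rich bands of Giemsa staining. G-negative bands held 57.2% of CAL27 regions and 56.4% of SCC13 regions, against 46.3% and 46.1% for placement on the same chromosomes (one-sided permutation p = 9.99e-04 for each, the smallest possible). The darkest bands, which are poor in genes, held 7.91% of shared regions, 8.95% of CAL27-only regions and 14.0% of SCC13-only regions. SCC13-only regions exceeded CAL27-only regions there by 5.09 points (95% interval 3.21 to 6.98; Fisher's exact test, adjusted p = 2.12e-08 over 6 tests).

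Neither width nor arm content accounted for the whole SCC13-only excess in the darkest bands. The odds ratio was 1.66 (95% interval 1.41 to 1.96) over all line-only regions, 1.58 (1.34 to 1.87) within 5 groups of width and 1.57 (1.33 to 1.87) within arms. These intervals treat regions as independent. The excess was not set against rotated class labels, so local runs of line-only regions were not tested as its cause. Placement without regard to bands could not account for all SCC13-only regions either, since 51.1% lay in G-negative bands against a placed mean of 45.9% and a maximum of 50%. Their 14.0% in the darkest bands lay above the shared regions and at the lowest of the placements (mean 17.2%, SD 0.967, minimum 14.0%). Centromeric or variable bands, left out of the placements, held 1.18% of SCC13-only regions (17 of 1438; 95% interval 0.690 to 1.89). They held 0.382% of shared regions (0.223 to 0.611) and 0.586% of CAL27-only regions (0.442 to 0.762), a difference that was not tested. Placement takes no account of open chromatin or mappability, which background can follow. These values therefore do not decide how many SCC13-only regions are background. Line-specific binding stays open as an untested biological explanation.

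The high sharing of the SCC13 list cannot be told apart from the way the lists were made. All overlapping regions, 100%, had the same start and end, and what put a region on a list is not given in the sources used here. Whether the SCC13 list holds the stronger part of a common set of sites was not decided, since strength was not measured. The shared percentage was 50.9% in the widest of 5 groups of CAL27 regions and 9.87% in the narrowest, but width is not strength, and merging over both lines would widen shared regions too.

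The longest run of neighbouring SCC13-only regions held 8 regions on chromosome 7 at 51392753 to 54177483, against a mean longest run of 4.30 after shuffling within arms (permutation p = 0.00300). The longest CAL27-only run held 25 regions on chromosome 9 at 86915126 to 89285667, against 19.5 (permutation p = 0.0559). The largest CAL27 cluster, of 7 regions, was set against the largest cluster of each placement within 500 kb (one-sided permutation p = 0.0519). Its size alone therefore did not pass 0.05. Of SCC13-only regions, 12.0% lay within 10 kb of a CAL27 region against 10.3% placed within 500 kb (permutation p = 0.00995), and of CAL27-only regions 8.37% lay within 10 kb of an SCC13 region against 5.86% (p = 0.00498, the smallest of 200 placements). Placed regions can fall on a region of the other line, which line-only regions cannot, and this raises the placed values.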
